A study of Mus musculus with 48 samples.

How the data were processed

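RNA was measured by polyA sequencing in α and β cells sorted from the islets of male mice at zeitgeber times 0, 4, 8, 12, 16 and 20 (ZT, hours after lights on), in control mice and in mice given doxycycline. Cell type, treatment and time make 24 groups of 2 libraries, 48 libraries in all. Per the labels, libraries were made from 300 ng of polyA RNA with a TruSeq kit that does not mark strand, and reads were demultiplexed with bcl2fastq and aligned with STAR to GRCm38. The dates in the labels' titles place the libraries in 2 sequencing runs. The earlier run holds replicate 1 of ZT4 to ZT20 (20 libraries), and the later run holds replicate 2 of every group together with both replicates of ZT0 (28 libraries).

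The deposited values are an estimated count per gene, one table per run, with 42713 genes and no scaling for depth. The program that counted the reads, and how it treated reads shared between genes, are not stated. Values of near-identical copies (insulin, interferon and MHC genes) and of overlapping or antisense genes are therefore uncertain where reads could be split between them. Of the nonzero values of a library, 53.5 to 73.8% were whole numbers (within 1e-06), and of the whole values up to 20 in a library, 99.7 to 100% were even, so 1 counted unit adds 2 at low values. A deposited RPKM table of each run was not used here, because it was scaled run by run. From the deposited estimated counts, rounded to whole numbers, CPM (library-scaled counts) and log2 CPM with a prior count of 2 were computed, with library sizes scaled by TMM factors. All 48 columns were matched to their labels by title, and 0 columns remained over.

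Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15) and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. Adjusted p-values are Benjamini-Hochberg values over all genes of a comparison, with a threshold of 0.05. α and β cells of control mice were compared with time (6 levels) and run as terms. The effect of doxycycline was fitted in each cell type with the same terms, and its difference between the cell types was fitted over all 48 libraries with time and run terms for each cell type. The effect was also tested for a difference between times. Rhythms were fitted in the 12 libraries of each condition as a cosine and a sine with a 24 h period plus the run, and the 2 coefficients were tested together. Amplitudes are the distance from the mean to the peak in log2 units and peaks are in hours after lights on. Differences of rhythm between conditions were tested through the interaction of both coefficients with treatment or cell type. The SE of a log2 fold change is its size divided by the square root of F, and the SE of an amplitude or a peak comes from the delta method.

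A total of 26 gene lists was fixed before the data were examined, as were the tests, the terms and the rule for naming genes. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with the correlation estimated from the data. Members past the threshold were counted with p-values adjusted over all genes and adjusted over the list alone. Genes are named by this rule: every clock gene that passed the filter; the 8 largest rises and 8 largest falls past the threshold with a mean of at least 10 CPM in the higher group and 1 direction at all 6 times; up to 4 members of each described list with the lowest p; the 8 genes with the lowest p in each rhythm or interaction test; and Gcg, Ins1, Ins2, Sst and Ppy. Predicted genes and antigen receptor segments were passed over. The genes below are the main ones of that set, and the few others are said to have been chosen after their values were seen.

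Total estimated counts per library ran from 16.1 to 69.9 M (M for mega). Between the 2 libraries of a group, the spread of counts was 21.6 to 105 times that of counting alone (χ² per degree of freedom, on halved counts), which includes the difference between the runs at 5 of the 6 times. The tests were checked on simulated counts with 200 genes changed by known amounts. The changed genes were drawn above a floor of mean counts, each gene was simulated independently, and no other effect of run, time or treatment was put in. The shares recovered therefore hold for a simpler setting than these data. For doxycycline in β cells, 71.6% of the genes simulated with a 1.5-fold change, 89.6% of those with a 2-fold change and 93.9% of those with a 4-fold change were recovered (15061 genes in the simulation). In α cells these shares were 79.1, 83.6 and 98.5% (14841 genes). For a difference of the doxycycline effect between times in β cells they were 2.99, 32.8 and 75.8% (15065 genes). Of the simulated rhythms in control β cells, 56% were recovered at an amplitude of 0.5 and 90% at an amplitude of 1 (13154 genes). For a difference of rhythm between control and doxycycline β cells the shares were 21 and 79% (15055 genes).

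Replicate numbers stand for the sequencing run at 5 of the 6 times, so the shared number there marks a shared batch, per the labels' titles. At these 5 times, deviations from the group means correlated between same-numbered control and doxycycline libraries at 0.0163 to 0.305 in β cells and at 0.0708 to 0.307 in α cells. At ZT0, where both replicates come from 1 run, these correlations were -0.387 and -0.481. Between same-numbered α and β libraries they were 0.04 to 0.395 in controls and 0.176 to 0.482 in doxycycline mice at these 5 times, and 0.273 and 0.419 at ZT0. With the run difference removed, the values at these 5 times were -0.157 to 0.0543 and -0.0829 to 0.131 between control and doxycycline libraries of β and of α cells, and -0.122 to 0.346 and -0.045 to 0.321 between α and β libraries of control and of doxycycline mice. All are correlations across genes, which are not independent replicates.

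Alternatives tried were other size factors, no count filter, no run term, a replicate block, each run alone, limma-voom, DESeq2 1.42.0, other models of time, hormone genes left out, covariates for other cell types, each replicate and each library left out. The macrophage covariate, the stellate cell covariate, the halved counts, the crossed block, run terms by treatment and the single runs for all but the doxycycline comparisons were chosen after seeing the data. Transgene transcripts were not analysed here, and the Per2 locus carries the luciferase fusion. The age of the libraries after the start of doxycycline is not in the labels, and part of the animals were on inverted light cycles for 2 weeks beforehand, which the labels do not assign to samples.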

Results

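α cells, which release glucagon, and β cells, which release insulin, were sorted by fluorescence from freshly isolated islets of mice whose β cells can be ablated with doxycycline. The animals carry fluorescent reporters for both cell types, a luciferase fused to the clock protein PER2, and a transgene pair through which doxycycline switches on diphtheria toxin A under the insulin promoter. Doxycycline mice received 300 mg of the drug in drinking water with 2% sucrose, and control mice received sucrose water alone. Both were kept on 12 h of light and 12 h of dark and were fed at night from 10 days before the experiment. No group received doxycycline without the toxin transgenes, so effects of the drug itself and of the ablation cannot be told apart. The series asks how circadian clocks bear on the regeneration of β cells after such an ablation. Cells were taken every 4 h at 6 zeitgeber times, with 2 libraries per cell type, treatment and time, so that each of the 4 conditions has 12 libraries. The labels speak of duplicates and do not say that the replicates come from separate animals, so the p-values measure only the spread between these libraries.

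Total estimated counts per library were 36.7 ± 14.6 M in control α cells, 37.9 ± 15.0 M in doxycycline α cells, 47.0 ± 20.1 M in control β cells and 40.9 ± 16.5 M in doxycycline β cells (SD, n = 12 each). By the dates in their titles the libraries come from 2 sequencing runs. The 20 libraries of the earlier run held 16.1 to 28.6 M and the 28 libraries of the later run held 37.4 to 69.9 M. Between 16325 and 19563 genes had a count in a library. Glucagon (Gcg) took 30.5 ± 3.10% of the counts in control α cells and 0.0169 ± 0.00489% in control β cells (SD, n = 12). Insulin 2 (Ins2) took 21.2 ± 2.87% in control β cells, 19.7 ± 2.55% in doxycycline β cells and 0.0489 ± 0.0715% in control α cells. Between the 2 runs 3254 of 15188 genes differed in β cells and 3229 of 14932 in α cells (edgeR). The run goes with the replicate number at 5 of the 6 times and with whatever else differed between the replicates, and it is a term in every comparison. On the first principal component of the β-cell libraries, which held 34.8% of the variance, controls lay between -67.8 and -8.0 and doxycycline libraries between 12.0 and 66.0.

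The first comparison asks what sets α and β cells apart in control mice. Insulin 2 was higher in β cells by a log2 fold change of 9.25 ± 0.41 and the transcription factor Mafa by 8.92 ± 0.39 (SE, n = 12 per group, adjusted p = 1.06e-14 for Ins2). Ucn3, a peptide of mature β cells, was higher by 9.06 ± 0.31. In the other direction, Gcg stood at 308200 ± 47600 CPM in α cells and 170 ± 55.0 CPM in β cells (SD, n = 12, log2 fold change -10.85 ± 0.27), and the α-cell transcription factor Irx1 had a log2 fold change of -10.12 ± 0.16. All 16 measured members of the β-cell identity list were higher in β cells (median log2 fold change 7.23) and all 8 of the α-cell identity list were lower (median -7.67). These lists passed with the preset correlation (camera adjusted p = 3.65e-29 and 1.04e-32) and with an estimated correlation (adjusted p = 0.000609 and 1.74e-06).

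In control β cells the lists of the unfolded protein response and of cholesterol synthesis lay higher, the latter with the preset correlation alone. All 18 measured genes of the unfolded protein response were higher in β cells (median log2 fold change 1.12), among them Edem1, which routes misfolded proteins to degradation (2.49 ± 0.07). Ero1lb, an oxidase of the endoplasmic reticulum that is counted in the β-cell identity list, was higher by 4.91 ± 0.08. The unfolded protein response list passed with the preset correlation (camera adjusted p = 2.27e-08) and with an estimated correlation (adjusted p = 0.0461, or 0.0678 under the replicate block). All 16 genes of cholesterol synthesis were higher, with a median of 1.04, among them Insig1 (2.47) and Msmo1 (2.49). Their list passed at an adjusted p of 3.39e-05 with the preset correlation, and not with an estimated correlation (adjusted p = 0.566). Of 19 core clock genes 11 were higher in β cells and 0 were lower, and the repressor Nr1d1 stood at 201 ± 154 CPM in β cells against a mean of 34.9 CPM in α cells (log2 fold change 2.70 ± 0.44, adjusted p = 1.21e-05). The clock list did not pass (camera adjusted p = 0.164 preset, 0.916 with an estimated correlation). All 20 genes of the G2/M list were higher (median 1.35, camera adjusted p = 0.0349, and adjusted p = 0.916 with an estimated correlation). Markers of macrophages and dendritic cells stood beside these, with 12 of 14 higher and 1 lower in β cells (median 2.98, camera adjusted p = 0.0538, or 0.0462 under the replicate block, and 0.916 and 0.782 with an estimated correlation), and 13 of 14 acinar markers were lower (median -2.2, camera adjusted p = 0.493, and 0.916 with an estimated correlation; 0 lower in the earlier run alone). Adjusted over the list alone, 14 acinar markers were lower and the other counts given here were the same.

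In all, 10674 of 14945 genes differed between control α and β cells (edgeR), 5105 higher and 5569 lower in β cells. Of these, 1657 and 1886 differed at least 2-fold. The list of δ, PP and ε cell genes was lower in β cells (6 of 7 members lower and 1 higher, median -1.37, camera adjusted p = 6.88e-06, and adjusted p = 0.0108 with an estimated correlation, or 0.0711 under the replicate block), with Ppy at a log2 fold change of -8.64 and Sst at -1.37.

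The second comparison asks how the β cells sorted from doxycycline mice differ from control β cells. Gpx3, a secreted glutathione peroxidase, rose from 106 ± 24.8 to 1181 ± 397 CPM (SD, n = 12), a log2 fold change of 3.47 ± 0.17 (SE, adjusted p = 1.78e-11). C1qtnf1, a secreted protein of the C1q family, rose by 4.05 ± 0.19, Pappa2, a protease of IGF-binding proteins, by 3.57 ± 0.22, Aldh1a3, a retinaldehyde dehydrogenase, by 3.41 ± 0.28, and the laminin chain Lama5 by 3.10 ± 0.16. Among the largest falls were Nynrin, from 252 ± 98.8 to 20.8 ± 12.3 CPM (log2 fold change -3.77 ± 0.35, adjusted p = 8.82e-08), the cation channel Trpm5 (-2.73 ± 0.29) and Gad1, which makes GABA (-2.48 ± 0.16). The hormone genes Ins1 and Ins2 had log2 fold changes of -0.03 ± 0.13 and -0.09 ± 0.13 (adjusted p = 0.879 and 0.60). On GRCm38, Gpx3 (ENSMUSG00000018339.11) lies on chromosome 11 from 54902453 to 54910377, C1qtnf1 (ENSMUSG00000017446.14) on chromosome 11 from 118428203 to 118449963, Aldh1a3 (ENSMUSG00000015134.15) on chromosome 7 from 66390890 to 66427517, and Nynrin (ENSMUSG00000075592.10) on chromosome 14 from 55854010 to 55874736.

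**Figure D1:**
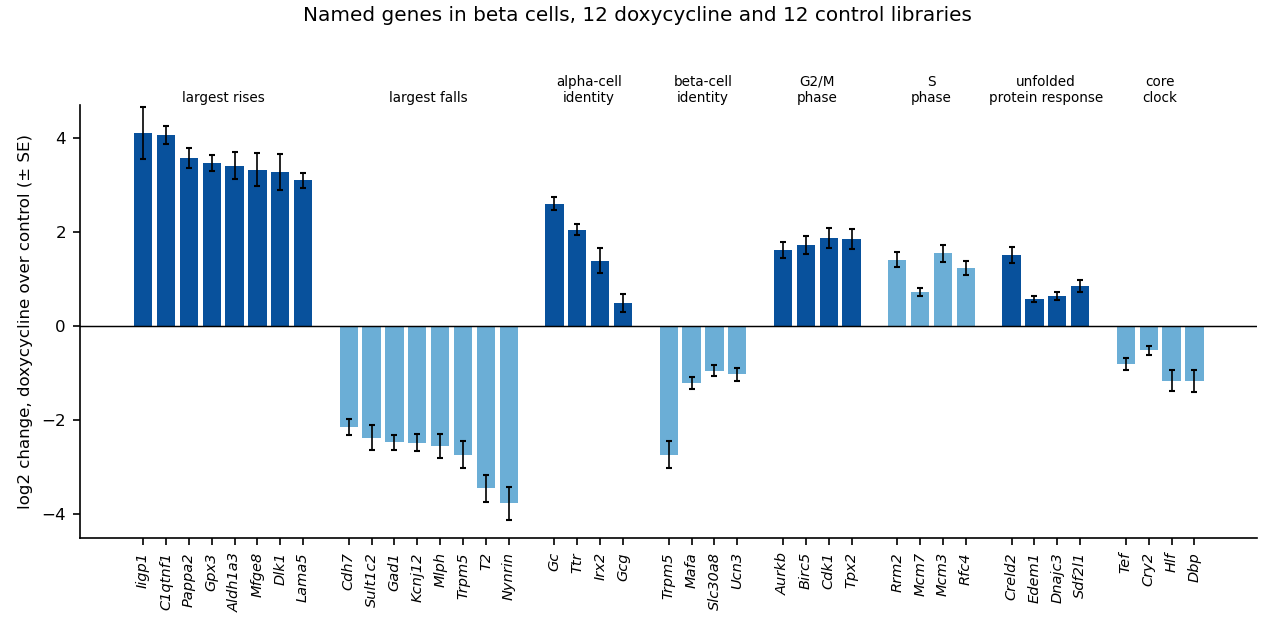
Log2 fold change of named genes in β cells, doxycycline over control, grouped by gene list. Bars give the fitted change, in shades that only part the gene groups, and error bars its SE, from 12 libraries per group; C1qtnf1 reached 4.05 and Nynrin -3.77.

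Doxycycline β cells had less of several β-cell genes and more of α-cell genes. In the β-cell identity list, 9 of 16 members fell and 3 rose (median log2 fold change -0.32), and the falls included Mafa (-1.22 ± 0.13, from 249 ± 96.5 to 102 ± 23.4 CPM), Ucn3 (-1.03 ± 0.14) and the zinc transporter Slc30a8 (-0.95 ± 0.11). The list passed with the preset correlation (camera adjusted p = 0.000681) and not with an estimated correlation (adjusted p = 0.398). In the α-cell identity list, 4 of 5 measured members rose (median 1.39, camera adjusted p = 1.89e-07, and 0.00185 with an estimated correlation). Gc, the vitamin D binding protein, rose from 65.7 ± 24.1 to 385 ± 111 CPM (2.60 ± 0.14, adjusted p = 4.08e-11), transthyretin (Ttr) by 2.05 ± 0.12 and Irx2 by 1.39 ± 0.26. The rise of Gcg, by 0.50 ± 0.19 (adjusted p = 0.0363), left it at 0.0238 ± 0.0088% of the counts. Its call was lost without any 1 of 11 libraries, namely controls at ZT4, ZT12, ZT16 and ZT20 replicate 1 and ZT8 replicate 2, and doxycycline libraries at ZT0, ZT4, ZT8, ZT12 and ZT20 replicate 1 and ZT16 replicate 2 (0.41 to 0.49, adjusted p = 0.0512 to 0.0829), and as a mean contrast over 12 groups, in the later run alone and with the macrophage covariate (0.35 to 0.50, adjusted p = 0.0681, 0.424 and 0.481). In the δ, PP and ε cell list 5 of 7 rose (median 0.64, camera adjusted p = 0.0259, and 0.503 with an estimated correlation), among them Ppy by 1.02 ± 0.17. Genes that are usually kept low in mature β cells rose in 8 of 9 cases (median 1.77, camera adjusted p = 5.19e-05, and 0.136 with an estimated correlation). Of 12 exocytosis genes 7 fell and 0 rose, among them Sytl4 (-0.77) and Stx1a (-0.64), with a camera adjusted p of 0.00774, and 0.0886 with an estimated correlation. Marker genes of macrophages and dendritic cells rose beside these in 15 of 15 cases (median 2.25, camera adjusted p = 3.12e-08, and 0.398 with an estimated correlation), with Cd74 at 46.6 ± 27.8 CPM in controls and 223 ± 108 CPM after doxycycline. Counts for β cells adjusted over the list alone equalled those over all genes in these lists.

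Genes of the cell cycle rose in doxycycline β cells. In the G2/M list 20 of 20 members rose (median log2 fold change 1.65), among them the mitotic kinase Cdk1, from 4.00 ± 1.35 to 15.5 ± 6.98 CPM (1.88 ± 0.22, adjusted p = 9.86e-07), Aurkb (1.62 ± 0.17) and Birc5 (1.73 ± 0.20). In the S phase list 19 of 20 rose and 1 fell (median 0.95), among them Rrm2, which makes deoxynucleotides (1.41 ± 0.15), and the replication helicase subunit Mcm3 (1.55 ± 0.17). Both lists passed with the preset correlation (camera adjusted p = 3.42e-17 and 6.03e-13) and not with an estimated correlation (adjusted p = 0.136 for each). Both held within each run, with 20 of 20 G2/M members higher in the earlier run (median 2.18) and in the later run (1.41), and 19 of 20 S phase members higher in each. The size of the rise differed between the runs for 12 G2/M members and 1 S phase member adjusted over the list alone, and for 0 over all genes. In the list of D cyclins and CDK inhibitors, which also holds CDK genes, 3 of 11 rose, among them the kinase Cdk6 (2.05 ± 0.24). In that list 4 fell (5 adjusted over the list alone), among them the cyclin Ccnd2 (-0.50 ± 0.07). In the list of p53 targets 5 of 10 rose (camera adjusted p = 0.00774, and 0.4 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 1.39 ± 0.20 and Phlda3 at 1.92 ± 0.24. In the unfolded protein response 11 of 18 rose and 0 fell (median 0.46, camera adjusted p = 0.000645, and 0.414 with an estimated correlation), among them Creld2, from 97.5 ± 36.6 to 296 ± 142 CPM (1.51 ± 0.17). The same libraries held the rise of the macrophage markers given above, which lay at a median of 2.29 in the earlier run and 2.17 in the later run. Stellate cell and fibroblast markers lay at 2.34 with 4 of 8 higher in the earlier run, and at 1.08 with 0 higher in the later run. Their list did not pass over both runs (camera adjusted p = 0.199, and 0.825 with an estimated correlation).

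Of the 19 core clock genes, 11 fell and 2 rose in doxycycline β cells, as an average over the 6 times (12 lower adjusted over the list alone). Dbp, an output gene of the clock, went from 73.8 ± 51.4 to 31.5 ± 19.6 CPM (log2 fold change -1.18 ± 0.23, adjusted p = 0.000328), and its relatives Tef and Hlf had changes of -0.80 ± 0.13 and -1.16 ± 0.22. Nr1d1 fell from 201 ± 154 to 101 ± 56.1 CPM (-0.997 ± 0.31, adjusted p = 0.0122), while Arntl, the activator of the core loop, had a change of 0.03 (adjusted p = 0.918). Bhlhe40 and Npas2 rose by 0.73 each. The call of Npas2 was lost without any 1 of 13 libraries, namely controls at ZT0, ZT4, ZT12 and ZT16 replicate 2 and both at ZT8 and ZT20, and doxycycline libraries at ZT0 and ZT20 replicate 2, ZT12 replicate 1 and both at ZT8 (0.58 to 0.73, adjusted p = 0.0532 to 0.0898), and with no run term, in each run alone and with Gcg as a covariate (0.67 to 0.82, adjusted p = 0.0551 to 0.260). The calls of Bhlhe40 and Nr1d1 were lost in each run alone, and that of Bhlhe40 with the macrophage covariate (0.64, adjusted p = 0.249). The list passed with the preset correlation (camera adjusted p = 0.00758) and not with an estimated correlation (adjusted p = 0.424). Within each run 8 clock genes were lower, at a median of -0.58 in the earlier run and -0.32 in the later run.

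The interferon response separated the 2 runs. Of 14 genes of the type I interferon list 9 rose in doxycycline β cells over both runs (median log2 fold change 1.45, camera adjusted p = 0.00122, and 0.503 with an estimated correlation), among them Bst2 (2.08 ± 0.30). Outside the list, Iigp1, an interferon-induced GTPase, rose by 4.11 ± 0.56. In the earlier run the median was 2.87 with 14 of 14 higher, and in the later run it was 0.51 with 3 higher. MHC class I genes had medians of 0.90 and 0.19 in these runs, and over both 4 of 9 rose (6 adjusted over the list alone, camera adjusted p = 0.0867, and 0.683 with an estimated correlation), with B2m at 1.39 ± 0.23. With the macrophage covariate the calls of Bst2 and B2m in β cells ended (1.12 and 0.77, adjusted p = 0.0512 and 0.114), and 1 interferon gene was called. A difference of the doxycycline effect between the runs was called for 2 interferon genes with p-values adjusted over all genes and for 13 adjusted over the list alone (edgeR). The acinar list had medians of -3.21 in the earlier run and 3.38 in the later run, with 0 and 6 genes higher. Over both runs 0 of its 13 genes passed, and the doxycycline effect differed between the runs for 13 of them adjusted over the list alone and 0 over all genes. The macrophage markers rose beside the interferon genes in both runs.

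**Figure D2:**
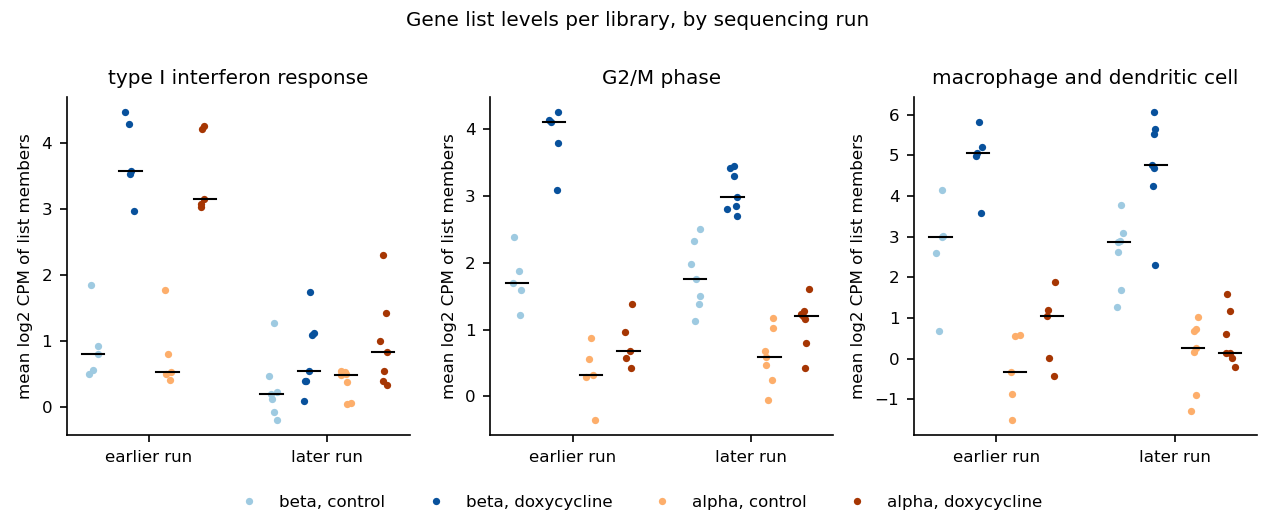
Mean log2 CPM of the interferon, G2/M and macrophage lists in each library, by cell type, treatment and sequencing run. Points are libraries and bars are medians; the interferon scores of doxycycline libraries stand apart in the earlier run, where the median change in β cells was 2.87 against 0.51 in the later run.

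In all, 7122 of 15188 genes changed with doxycycline in β cells (edgeR), 3620 higher and 3502 lower, and 1311 and 223 of them changed at least 2-fold. The earlier run taken alone gave 4638 genes and the later run gave 3747, and with the mean of the macrophage markers as a covariate, chosen after seeing the data, 3639 genes passed. Across genes, which are not independent replicates, the changes in the 2 runs correlated at 0.781.

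The third comparison asks the same of α cells, in which the insulin promoter does not drive the toxin. Fewer genes passed than in β cells, and interferon and antigen presentation genes were among them. B2m, the light chain of MHC class I, rose from 57.9 ± 23.4 to 293 ± 261 CPM (log2 fold change 1.81 ± 0.31, SE, n = 12 per group, adjusted p = 0.0178). Ifit3 rose by 2.61 ± 0.41, Usp18 by 0.74 ± 0.11 and Aldh1a3 by 2.34 ± 0.36, the last from 0.278 to 1.55 CPM (adjusted p = 0.00763 for each). Under the replicate block the calls of B2m and Aldh1a3 ended (adjusted p = 0.0974 and 0.0541), and with the ZT0 numbers crossed they held (adjusted p = 0.0391 and 0.0256). Otof, a calcium sensor of vesicle fusion, went from 16.1 ± 4.35 to 9.61 ± 2.83 CPM (-0.78 ± 0.12, adjusted p = 0.00763) and Frrs1l by -0.53 ± 0.08. Gcg had a log2 fold change of 0.06 ± 0.09 (adjusted p = 0.958). B2m (ENSMUSG00000060802.8) lies on chromosome 2 of GRCm38 from 122147686 to 122153083.

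In the interferon list of α cells 2 of 13 genes rose with p-values adjusted over all genes and 13 adjusted over the list alone (median log2 fold change 1.27, camera adjusted p = 4.71e-35, and 0.0142 with an estimated correlation). The MHC class I list had 1 of 9 (0 under the replicate block), or 6 adjusted over the list alone (camera adjusted p = 6.07e-11, and 0.0835 with an estimated correlation). Within the earlier run the interferon median was 2.68 with 13 of 13 higher, and within the later run it was 0.41 with 0 called. The G2/M list had a median of 0.50 with 0 of 20 called and 1 adjusted over the list alone (camera adjusted p = 1.13e-12, and 0.12 with an estimated correlation, or 0.0316 under the replicate block). The S phase list had a median of 0.13 with 0 of 20 called (camera adjusted p = 0.00118, and 0.362 with an estimated correlation). None of the core clock genes was called in α cells, over all genes or over the list alone (median -0.07, camera adjusted p = 0.21). Macrophage markers had a median of 0.69 with 0 of 12 called (camera adjusted p = 7.21e-05, and 0.259 with an estimated correlation). Lists of other cell types were also higher with the preset correlation and not with an estimated one, namely stellate cells and fibroblasts (camera adjusted p = 0.00606, and 0.259), δ, PP and ε cells (0.0184, and 0.113), β-cell identity (0.0232, and 0.491) and ductal cells (0.0366, or 0.0549 under the replicate block, and 0.192). The same held for the unfolded protein response (1.18e-06, and 0.155), mitochondrially encoded genes (0.00327, and 0.362) and p53 targets (0.0247, and 0.31), which were higher, and for oxidative phosphorylation (0.00606, and 0.506) and glycolysis (0.048, or 0.0669 under the replicate block, and 0.526), which were lower.

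In all, 19 of 14932 genes changed with doxycycline in α cells (edgeR), 12 higher and 7 lower, against 1173 genes with an unadjusted p under 0.05. The earlier run alone gave 132 genes and the later run alone gave 0 (740 with an unadjusted p under 0.05). The replicate block gave 7 genes, all of them among the 19, and 42 with the replicate numbers of doxycycline libraries crossed at ZT0, where same-numbered libraries deviated in opposite directions. DESeq2 gave 125 and no filter on counts 56, the macrophage covariate gave 0 (840 with an unadjusted p under 0.05), and leaving out single libraries gave 9 to 35. Across genes, the changes in the 2 runs correlated at 0.0606.

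**Figure D3:**
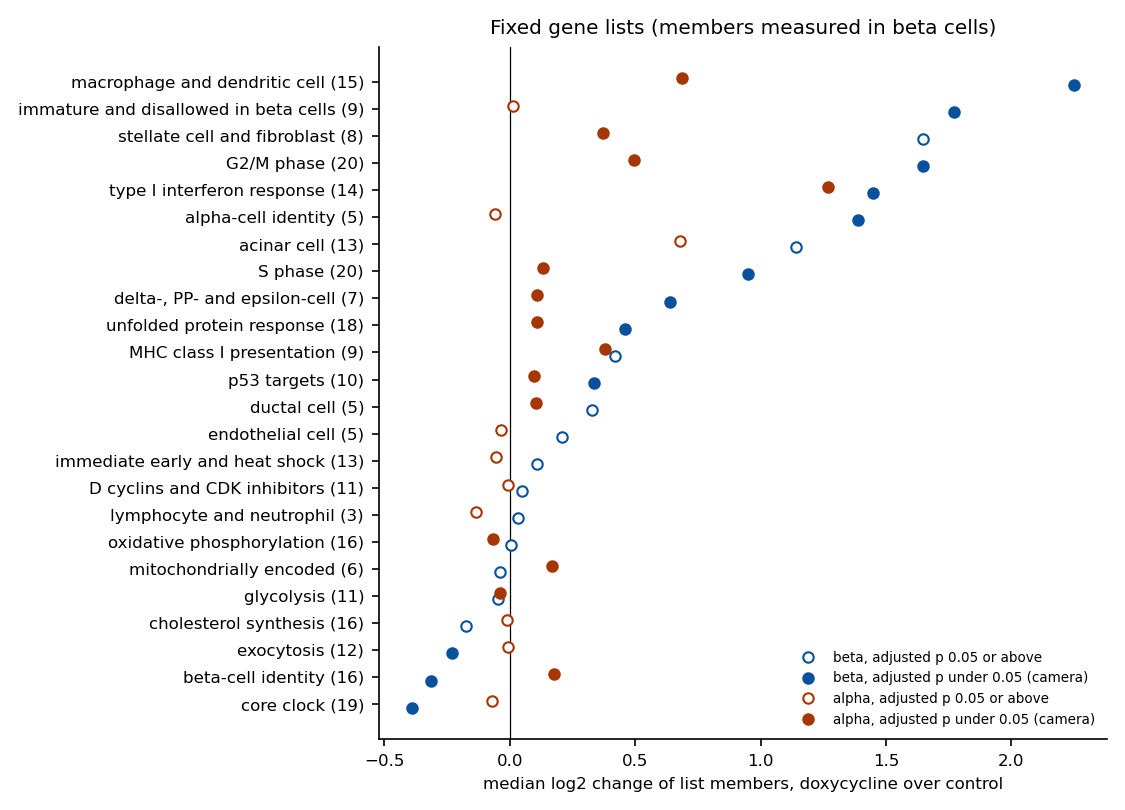
Median log2 change of the members of each gene list, doxycycline over control (x axis), in β cells (blue) and α cells (red), with filled points where the camera adjusted p with the preset correlation was under 0.05 and the number of members measured in β cells beside each name. The macrophage list lay at 2.25 in β cells and 0.69 in α cells, and the interferon list at 1.45 and 1.27.

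The fourth comparison asks which effects of doxycycline differed between β and α cells. Gpx3 changed more in β cells, by 3.24 ± 0.20 on the log2 scale, as did C1qtnf1 (3.89), Pappa2 (3.51), Gc (2.27 ± 0.15, adjusted p = 1.17e-13) and Ttr (2.01 ± 0.18). Of 8 α-cell identity genes 5 changed more in β cells (6 adjusted over the list alone, median 0.81, camera adjusted p = 3.23e-09, and 0.000234 with an estimated correlation). In the G2/M list 18 of 20 genes differed toward a higher change in β cells (20 adjusted over the list alone, median 1.03, camera adjusted p = 7.04e-09, and 0.325 with an estimated correlation), with Cdk1 at 1.37, and in the S phase list 17 of 20 with 1 lower (18 adjusted over the list alone, camera adjusted p = 1.5e-09, and 0.131 with an estimated correlation). Of the core clock genes 8 changed toward a lower level in β cells (median -0.45, camera adjusted p = 0.00885, and 0.402 with an estimated correlation), among them Per3 (-1.14) and Dbp (-0.997). In the earlier and the later run alone 4 and 0 of these clock genes were called, 3 and 3 α-cell identity genes, 17 and 3 G2/M genes, 14 and 7 S phase genes, and 1 and 6 macrophage markers. In the interferon list 0 of 15 differed between the cell types (median -0.18, camera adjusted p = 0.896). Macrophage markers differed in 8 of 15 cases, each with a larger change in β cells (9 adjusted over the list alone, median 1.56, camera adjusted p = 0.000504, and 0.566 with an estimated correlation). In all, 4126 of 16207 genes differed (edgeR), 2053 toward a higher and 2073 toward a lower change in β cells.

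The fifth comparison asks whether the effect of doxycycline depended on the time of day. No gene passed in β cells (edgeR, 0 genes, 394 with an unadjusted p under 0.05; DESeq2, 10 genes) and none in α cells (edgeR, 0 genes, 196 with an unadjusted p under 0.05; DESeq2, 5 genes; edgeR with no filter on counts, 74 genes). Both unadjusted edgeR counts lie below a share of 0.05 of the genes tested (15188 and 14932), the share expected with no effect. The gene with the lowest p in β cells was Rbm15b, and among the lowest stood Herpud1 of the unfolded protein response. Taken at each time alone, doxycycline changed 1208 genes at ZT0, 1324 at ZT4, 297 at ZT8, 98 at ZT12, 691 at ZT16 and 414 at ZT20 in β cells, each from 2 against 2 libraries with the spread pooled over all groups.

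The sixth set of comparisons asks which transcripts followed a 24 h rhythm in each condition. Arntl and Cry1, of the core loop of the clock, were rhythmic in all 4 conditions. Arntl peaked near lights on, with an amplitude of 1.38 ± 0.16 (log2, SE, n = 12) and a peak at 22.8 ± 0.4 h in control β cells, 1.19 ± 0.15 and 1.2 ± 0.5 h in doxycycline β cells, 1.34 ± 0.18 and 0.6 ± 0.5 h in control α cells, and 1.40 ± 0.21 and 0.4 ± 0.5 h in doxycycline α cells (adjusted p = 0.00801, 0.00701, 0.00549 and 0.0145). Cry1, a repressor of the loop, had amplitudes of 0.91 ± 0.12 and 1.20 ± 0.12 in control and doxycycline β cells, with peaks at 19.5 ± 0.5 and 22.0 ± 0.4 h. The call of Cry1 in control β cells was lost without ZT8 replicate 1 (0.92, adjusted p = 0.0577), and that of Arntl in doxycycline α cells without ZT20 replicate 1 (1.36, adjusted p = 0.0560). Of 19 measured clock genes 9 were rhythmic in control and 9 in doxycycline β cells, and of 17 in α cells 13 were rhythmic in controls and 13 after doxycycline (13, 11, 16 and 15 adjusted over the list alone). Fitted in each run alone, the peaks of 8 of the 9, 9 of the 9, 11 of the 13 and 13 of the 13 lay within 2 h of each other. Arntl (ENSMUSG00000055116.8) lies on chromosome 7 of GRCm38 from 113207465 to 113314126.

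**Figure D4:**
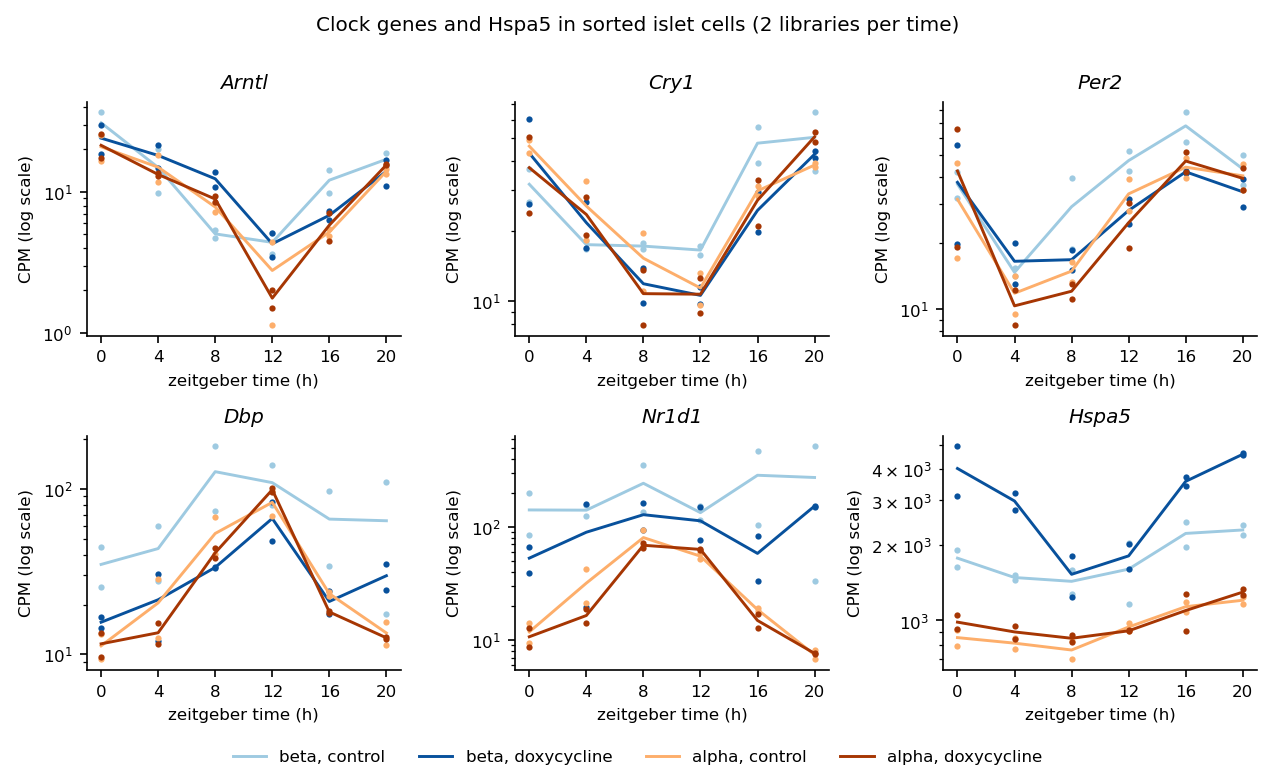
CPM (log axis) of the clock genes Arntl, Cry1, Per2, Dbp and Nr1d1 and of the chaperone Hspa5 against zeitgeber time, in the 4 conditions. Points are libraries and lines join the means of 2 libraries; Arntl had amplitudes of 1.19 to 1.40 in the 4 conditions.

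Nr1d1, a repressor of Arntl, had an amplitude of 1.72 ± 0.11 with a peak at 9.0 ± 0.2 h in control α cells (adjusted p = 3.12e-05) and 1.66 ± 0.15 with a peak at 9.6 ± 0.3 h in doxycycline α cells. In β cells its fitted amplitude was 0.13 in controls (adjusted p = 0.963) and 0.09 after doxycycline (adjusted p = 0.971), with replicates far apart, as in control β cells at ZT16 (466 and 104 CPM) and ZT20 (511 and 33 CPM). Fitted in the earlier and the later run alone, its amplitudes in β cells were 0.59 and 0.63 in controls, with peaks at 18.1 and 5.8 h, and 0.36 and 0.56 after doxycycline, with peaks at 3.6 and 16.3 h (adjusted p = 0.387, 0.894, 0.344 and 0.802). Genes of the unfolded protein response were rhythmic in 2 of 18 cases in control β cells, 13 of 18 in doxycycline β cells, 9 of 17 in control α cells and 3 of 17 in doxycycline α cells (7, 14, 11 and 12 adjusted over the list alone). Those called in doxycycline β cells had a mean peak at 21.2 h, among them the chaperone Hspa5 (amplitude 0.81 ± 0.11, peak 21.3 ± 0.5 h, adjusted p = 0.00956). Genes of cholesterol synthesis were rhythmic in 2 of 16 cases in control β cells, 8 in doxycycline β cells with a mean peak at 13.3 h, 5 in control α cells with a mean peak at 20.2 h, and 2 in doxycycline α cells (5, 11, 10 and 8 adjusted over the list alone). Among other genes with the lowest p were Cpt1a, the entry step of mitochondrial fat oxidation, in control β cells (0.75 ± 0.07, peak 7.6 ± 0.3 h, adjusted p = 0.00511), the cold-inducible Rbm3 (1.14, 7.3 h) and Cirbp (1.05, 7.0 h) in doxycycline β cells, and the lipase Lpl in α cells of controls (0.85 ± 0.08, 3.1 ± 0.3 h).

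In all, 288 of 13302 genes were rhythmic in control β cells, 1576 of 13613 in doxycycline β cells, 600 of 13349 in control α cells and 375 of 13280 in doxycycline α cells (edgeR). The lists of control and doxycycline β cells shared 173 genes, against 34.4 for independent lists, with a median peak difference of 1.61 h. Those of control and doxycycline α cells shared 168, against 17 for independent lists, with a median difference of 0.926 h. Those of control β and α cells shared 92, against 11.8 for independent lists. Same-numbered control α and β libraries deviated alike at most times, as given above, so independence is not shown to hold for that last figure. Under the replicate block the count in doxycycline β cells was 688. The counts rest on few libraries. With a single library left out they ran from 20 to 893 in control β cells, 112 to 2317 in doxycycline β cells, 179 to 1141 in control α cells and 41 to 560 in doxycycline α cells, and with time as 6 levels they were 33, 0 (1876 with an unadjusted p under 0.05), 73 and 14.

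**Figure D5:**
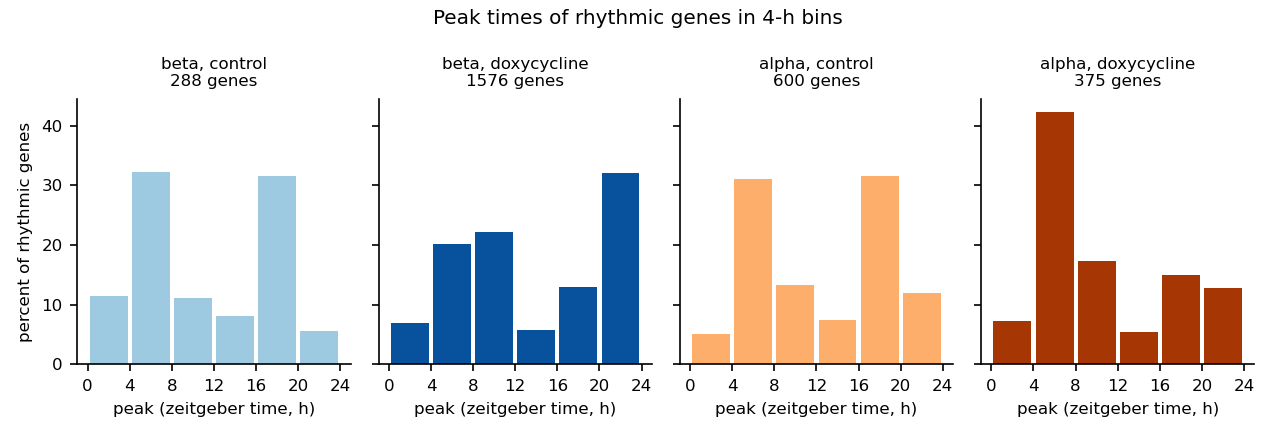
Percent of the rhythmic genes of each condition whose fitted peak lies in each bin of 4 h of zeitgeber time, from 288, 1576, 600 and 375 genes. In doxycycline α cells 42.4% peaked between ZT4 and ZT8, and in doxycycline β cells 32.1% between ZT20 and ZT24.

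The last set of comparisons tests differences of rhythm directly. Between control and doxycycline β cells 0 genes passed (edgeR, 708 with an unadjusted p under 0.05; limma-voom, 0 genes). Between control and doxycycline α cells 0 passed (edgeR, 377 with an unadjusted p under 0.05; limma-voom, 0 genes), and between α and β cells of control mice 0 passed (edgeR, 946 with an unadjusted p under 0.05; limma-voom, 0 genes). The unadjusted counts between control and doxycycline cells lie below a share of 0.05 of the genes tested (15188 and 14932), and that between α and β cells above it (14945). So the counts of rhythmic genes above are not shown to differ gene by gene. Cry1 and Arntl had unadjusted p-values of 0.00284 and 0.00562 for a difference between control and doxycycline β cells (edgeR, adjusted p = 0.929 for Cry1). Of the unfolded protein response 4 genes differed between these conditions adjusted over the list alone and 0 over all genes, with Herpud1 at an unadjusted p of 0.000371. Between α and β cells of controls Nr1d1 had an unadjusted p of 0.000249 and an adjusted p of 0.128 and was the 1 clock gene called adjusted over the list alone, and the lowest p belonged to Dapl1 (adjusted p = 0.0938). Under the replicate block 1 gene passed there, Jam2 (adjusted p = 0.0402). With the library of control β cells at ZT20 replicate 2 left out, 58 genes passed in that last comparison.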

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

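The tests of α-cell content, of β-cell share, of the run, with the macrophage covariate and of joint swaps in this part were chosen after the results were seen; the other splits of the samples were set before.

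The doxycycline effect differed between β and α cells for 4126 genes in a direct test of the interaction (edgeR). In 39 other draws, treatment labels were swapped within pairs of the same cell type, time and replicate number, and the highest count was 111. In 39 that swapped them jointly for the α and β libraries of a time and replicate number it was 1. These draws stand for no doxycycline effect in either cell type, rather than an equal effect in both. They therefore cannot exclude chance for a difference of that effect between the cell types. Among the genes with the lowest p in this test, the change in β cells exceeded that in α cells on the log2 scale by 3.89 for C1qtnf1, 3.61 for Cav2, 3.51 for Pappa2, 3.24 for Gpx3, 2.45 for Kdelr3, 2.27 for Gc, 2.18 for Rasgrf2 and 1.97 for Ldlrad3. Among clock genes the same difference was -1.14 for Per3, -0.997 for Dbp, -0.98 for Hlf, -0.67 for Tef, -0.63 for Nr1d2, -0.56 for Bhlhe41, -0.47 for Rora and -0.45 for Cry2. In the later run alone the calls of all of these clock genes were lost, and in the earlier run alone those of Per3, Dbp, Hlf and Tef, with differences of -0.80 and -1.28 for Per3 and -1.19 and -0.80 for Dbp in the earlier and the later run.

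The α-cell identity list stood out because its change differed between the cell types, with a median difference of 0.81 on the log2 scale and a camera p that held with both correlations. Carry-over of α cells into the doxycycline β-cell libraries is argued against by glucagon, the most abundant α-cell transcript. The rise of Gcg corresponds to 0.0204% of α-cell RNA in the doxycycline β-cell libraries. That share of α-cell RNA would supply a median of 0.1133% of the rise of the 3 other called members, and at most 2.67%. A lower share of β cells that raised the markers of all other cell types alike is argued against by their list medians. These lay apart by 2.046, from 0.21 for endothelial to 2.25 for macrophage markers. All of these medians rose, however, so a lower share with an uneven rise of other cells is not covered. Ins1 and Ins2 stayed within 0.0902 of no change, which lies within their SE and cannot show a small loss of β-cell share. What stays open is a change within β cells, as a hypothesis, or an uneven admixture of other cells that also express Gc, Ttr or Irx2, which was not tested.

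The doxycycline effect also differed between the 2 sequencing runs, in a direct test of the interaction, for 7 genes in β cells and 17 in α cells (edgeR), of which 2 and 4 belong to the interferon list. An artefact of the run or of library preparation would shift controls too, but the run difference of the list in controls was 0.2009 of that in doxycycline libraries in β cells and 0.1103 in α cells. With the macrophage and dendritic cell markers as a covariate within the earlier run, 11 of 15 interferon genes passed as higher in β cells (15 without it, median 2.38 against 2.98). The count over all genes went from 4638 to 1767. This argues against those cells as the whole source in that run alone, from 5 libraries per group. Over both runs the covariate left 1 interferon gene called in β cells, as given above. In α cells 1 of 15 passed within the earlier run (14 without it, median 2.25 against 2.64), while the count over all genes went from 132 to 6. There macrophages and dendritic cells cannot be told apart from a response of α cells with 5 libraries per group. The rule for this test asked that the calls hold in each cell type, so it was not met. A difference between the mice, days or doxycycline courses of the 2 runs, which the labels do not record, may be behind the pattern and stays open as untested.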

How the results depend on the processing

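Tests with single runs outside the doxycycline comparisons, the macrophage covariate, halved counts and the crossed block were chosen after seeing the data. In the comparisons of groups, the direction of every named gene past the threshold held in all settings run, with 0 reversals. Over all comparisons, uncalled genes included, 8424 of 8929 values of named genes under other settings stayed on their side of the threshold (398 lost it, 107 gained it). Among called genes, those for doxycycline in β cells kept 1295 of 1377 such values and those in α cells 131 of 195. With a replicate left out these were 158 of 195 and 7 of 27, and rhythms in doxycycline β cells kept 15 of 52. Other size factors, hormone genes left out and halved counts kept the number of genes past the threshold within 1.5 times in each comparison. So did limma-voom, which was run for the tests of rhythm only. Counts of list members moved by over 1.5 times in 5, 8 and 3 of 208 cases under the first 3 of these settings. For doxycycline in β cells (7122 genes) the earlier run alone gave 4638, the later run alone 3747 and the macrophage covariate 3639. For doxycycline in α cells (19) the count was 56 with no filter, 12 with no run term, 125 with DESeq2, 10 as a mean contrast over 12 groups, 10 with the insulin covariate, 0 with the macrophage covariate, 132 in the earlier run and 0 in the later run. The difference between the cell types (4126) gave 2139 in the earlier run and 1243 in the later run. The difference between times (0) gave 10 in β and 5 in α cells with DESeq2, and 74 in α cells with no filter. Rhythmic genes in control β (288), doxycycline β (1576), control α (600) and doxycycline α cells (375) numbered 33, 0, 73 and 14 with time as 6 levels, and 0, 0, 1 and 0 in the later run. With no run term the last 3 conditions gave 328, 344 and 166, in the earlier run they gave 146, 26 and 62, and with no filter doxycycline β cells gave 831. Differences of rhythm between control and doxycycline β cells, control and doxycycline α cells, and α and β cells (0 each) gave 1, 1 and 3 with no filter, and the first gave 1 in the earlier run. Gene lists past the threshold went from 12, 14 and 10 (β cells, α cells, difference) to 1 each with an estimated correlation. The replicate block gave 7 genes for doxycycline in α cells, 688 rhythmic genes in doxycycline β cells and 1 gene whose rhythm differs between α and β cells, and among 25 lists each it changed 2 calls in α against β cells, 2 for doxycycline in α cells and 1 for the difference with the preset correlation, and 2, 1 and 2 with an estimated one. It moved 7 of 208 counts of list members by over 1.5 times, against 13 with DESeq2. In the earlier and the later run alone 44 and 40 of 208 moved, and 48 and 40 did without replicate 1 and without replicate 2. The macrophage covariate moved 20 of 104. The replicate block ended the calls of 9 named genes for doxycycline in α cells and 3 for the difference between cell types. It also ended 2, 1 and 2 rhythms in doxycycline β, control α and doxycycline α cells. It brought past the threshold mt-Nd1 between the cell types, Per2 for doxycycline in β cells (adjusted p = 0.0486), the rhythms of Tef, Bhlhe40, Ddit3 and Nr4a1 in control β cells and of Per1 and Bhlhe41 in control α cells, and Jam2 in the difference of rhythm between cell types; it changed no other call. The block with the numbers crossed at ZT0 gave 7013 genes for doxycycline in β cells, 42 in α cells and 4355 for the difference, and 0 for differences between times or of rhythm. With a replicate or a single library left out, the ranges were 3147 to 7207 (doxycycline, β), 0 to 63 (doxycycline, α), 924 to 4289 (difference), 0 to 893, 0 to 2317, 20 to 1141 and 1 to 560 (rhythms in the order above), and 0 to 1, 0 to 19 and 0 to 58 (differences of rhythm). Single libraries moved these counts by over 1.5 times as follows, r1 and r2 being the replicates. Doxycycline in α cells: control ZT12 r2 9, ZT16 r1 11 and ZT20 r1 11; doxycycline ZT12 r1 12, ZT12 r2 35, ZT16 r1 12, ZT16 r2 12 and ZT20 r1 11. Rhythms in control β cells: ZT0 r2 147, ZT4 r1 60, ZT4 r2 172, ZT8 r1 20, ZT8 r2 147, ZT12 r2 68, ZT16 r1 26, ZT16 r2 63, ZT20 r1 60 and ZT20 r2 893. In doxycycline β cells: ZT4 r1 932, ZT8 r1 252, ZT8 r2 419, ZT12 r1 500, ZT12 r2 1029, ZT16 r1 609, ZT20 r1 112 and ZT20 r2 802. In control α cells: ZT0 r1 1141, ZT8 r1 200, ZT12 r2 291, ZT16 r1 306, ZT16 r2 260, ZT20 r1 201 and ZT20 r2 179. In doxycycline α cells: ZT4 r1 179, ZT8 r1 204, ZT8 r2 65, ZT12 r1 195, ZT12 r2 150, ZT16 r1 151 and ZT20 r1 41. Differences of rhythm: 1 without doxycycline β cells at ZT0 r1; between cell types, 58 without β cells at ZT20 r2, 3 without those at ZT12 r1, and 1 without each of β cells at ZT0 r1, ZT4 r1 and ZT20 r1 and α cells at ZT20 r2. Single runs and left-out replicates hold fewer libraries; otherwise the cause was not tested. Differences between times were not run without a replicate, since no residual degrees of freedom remain.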

Other observations

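All tests of clock phase and amplitude, and the tests of the run, of α cells and with the macrophage and stellate covariates below, were chosen after the results were seen; the splits of the samples were set before.

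Clock genes of β cells peaked later after doxycycline in 1 of 2 versions of a permutation test over the whole list. With each gene's level in each condition and run removed first, the shared phase of the 19 clock genes in doxycycline β cells lay 1.56 h after that in control β cells, with 19 of 19 genes later in the fit over both runs, genes with no called rhythm such as Nr1d1 included (permutation p = 0.0161 over 4096 swaps of treatment within 12 pairs of time and replicate number, adjusted p = 0.0322 over 4 such tests). With the levels kept, which also differed between the conditions, the permutation p was 0.224, so the delay rests on how levels are treated. Fitted in each run alone, the delay was not shared by every gene. In the earlier run Clock, Cry2, Dbp and Tef peaked earlier after doxycycline (Dbp at 10.9 against 12.8 h, Tef at 12.8 against 13.5 h, Cry2 at 12.0 against 13.1 h), as did Ciart in the later run. In α cells the same shift was 0.07 h, with 14 of 19 genes later (permutation and adjusted p = 0.860). In doxycycline mice β cells lay 0.82 h after α cells, with 14 of 19 genes later (permutation p = 0.0147, adjusted p = 0.0322; 0.225 with levels kept), and in controls they lay at -0.72 h, with 7 of 19 later (permutation p = 0.0493, adjusted p = 0.0658; 0.409 with levels kept). The mean fitted amplitude of the 19 clock genes in doxycycline β cells was 0.681 of that in doxycycline α cells. Its permutation p was 0.000488, the smallest these swaps can give (adjusted p = 0.00195), and 0.00147 with levels kept. In controls this ratio was 0.802 (permutation p = 0.0981, adjusted p = 0.196). Between control and doxycycline cells the ratio was 0.891 in β cells and 1.05 in α cells (permutation p = 0.598 and 0.623). These ratios come from fits over both runs and include genes with no called rhythm. In doxycycline β cells Nr1d1 peaked at 3.6 and 16.3 h and Ciart at 2.1 and 18.3 h in the earlier and the later run. Peaks so far apart lower an amplitude fitted over both runs. The 9 called clock genes there peaked within 2 h in the 2 runs.

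Immediate early and heat shock genes, which respond to handling of cells, differed between libraries of 1 group and did so alike in both cell types. At ZT0 their mean log2 CPM in control replicate 1 was 6.67 in α and 5.57 in β cells, against 3.46 and 3.05 in replicate 2. In doxycycline mice at ZT0 the order was the other way round, with 6.61 and 4.78 in replicate 2 against 4.14 and 2.96 in replicate 1. At ZT4 to ZT20 the library of the earlier run had the higher level in all 20 pairs, and with time as a term the median log2 differences between the runs were 1.74 in control β cells, 1.55 in doxycycline β cells, 2.14 in control α cells and 2.47 in doxycycline α cells.

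The rise of S phase and G2/M genes in doxycycline β cells was set against cells of other types and the run. Macrophages and dendritic cells are argued against as its whole source, since 38 of the 40 members of the 2 lists remained higher with their markers as a covariate (39 without it). The median was 1.26 against 1.42, while the count over all genes went from 7122 to 3639. With the stellate cell and fibroblast markers, whose list lay at a median of 1.65, 39 remained (median 1.32, 6287 genes in all). The mean log2 CPM of these markers varied widely between replicates, as in doxycycline β cells at ZT4 (4.82 and -2.30). So noisy a covariate can take up little, and this test cannot decide on stellate cells and fibroblasts. The sequencing run is argued against by the lower of the 2 runs' medians, 1.115, with 39 members higher in each run. α cells are argued against because 39 of the 40 members had a lower level in doxycycline α cells than in doxycycline β cells. More cycling among the β cells of doxycycline mice is a hypothesis for this rise, found and tested on the same data. Stellate cells and fibroblasts, and dividing cells of types not tested here, stay open.

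The counts of the other comparisons were set against 99 other draws of the labels each. For control α against β cells the real count was 10674 genes and the highest other draw 9334 (1 of 12 pairs swapped). For doxycycline these were 7122 and 2660 in β cells (2 of 12 pairs swapped), and 19 and 1 in α cells. No other draw reached the real count in any of them, a share of 0.01 each with the real one included. The draws thus speak against chance and do not exclude it. The 19 genes of α cells still depend on the run and the settings, as given above. For rhythms, times were shuffled within runs in 99 draws. The real counts and the highest draws were 288 and 1 in control β cells, 600 and 463 in control α cells, and 375 and 89 in doxycycline α cells. The share was 0.01 in each of these, which speaks against chance and does not exclude it. With a single library left out, the real counts fell as low as 20, 179 and 41. In doxycycline β cells the real count was 1576 and the highest draw 2072, 2 of the 100 being as large with the real one included. That share of 0.02 lies under the 0.05 set beforehand. A shuffle of the times still gave a larger count, so chance is not excluded there either. For differences of rhythm the real counts were 0, which each of the 100 draws reaches by construction, so the draws decide nothing there. The highest counts of other draws were 1489 between control and doxycycline β cells, 16 between control and doxycycline α cells and 7795 between α and β cells of controls. Draws that call so many genes point to a structure of the samples. In the highest draws of the first and the last of these comparisons 4 of the 12 pairs had their labels swapped. Such swaps can spread the large difference in level between the groups unevenly over the times. Whether this gave the high counts was not tested.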
